A study of Drosophila melanogaster with 35 samples.

How the data were processed

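Values were deposited for 35 two-colour cDNA arrays of Drosophila melanogaster Kc167 cells in 13 groups. They cover Dam-Lam and Dam-Lam delta CaaX over Dam in untreated cells, DamID with and without ecdysone, DamID with and without trichostatin A (TSA), mRNA with over without ecdysone, and mRNA over genomic DNA. The deposited values are log ratios of both channels of each array, taken here as log2; per the submitters' processing notes they were made with limma, and its version, background correction, normalization, spot filter, log base and ratio direction are not given in the sources used here. Per the labels' protocols, total RNA was extracted with TRIzol and mRNA was amplified with a T7 system. Each array gave 7542 to 8485 rows with a value, and no spot intensities were used here, so measurement error could only be judged from the spread between arrays.

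Whether the arrays of a group share 1 direction was read from the values. In most groups arrays with exchanged dyes correlate positively, so their values were used unchanged. The correlation does not show which channel is over which. Channel 1 over channel 2 of the labels was assumed. The 6 Dam-Lam over Dam arrays of the ecdysone experiment do not settle their direction, and were used as deposited, with alternatives in which 3 of the 6, or every Cy3 array of that experiment, are multiplied by -1. Each array was centred on its median. Rows were named from the probe table, and rows of the same gene were averaged, giving 8421 units, 7258 of them genes with a symbol (550 with more than 1 row). Rows naming several genes and rows not in the table were kept without a gene name. The reference annotation (Release 6) was matched by gene number for 7135 genes and was used only for current symbols and gene order; it changed 0 symbols.

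Each comparison was a linear model fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with a gene-wise dye term. A unit needed a value on at least 75% of the arrays of a fit. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all units of the fit. Lam and Lam delta CaaX ratios were tested against 0 on 4 arrays each, and their difference on the 8 arrays together. The 10 ecdysone DamID arrays were fitted as 1 model of 4 DNA samples, and the 10 TSA arrays as 1 model of 6 DNA samples. The effect of a treatment on a fusion protein is its change minus the change of Dam alone. The mRNA response to ecdysone was tested on 5 arrays. The 2 arrays of mRNA over genomic DNA were not tested across arrays; medians of gene sets were set beside 10000 random sets of the same size. With the direction of the ecdysone arrays unsettled, Lam ratios within that experiment were not used to call genes.

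There were 25 gene lists, given by symbols, older symbols or symbol patterns: ecdysone response, cell death, ecdysteroid synthesis, ribosomal protein, proteasome, oxidative phosphorylation, cell cycle and replication, hemocyte, immune response, neuronal, muscle, fat body and yolk, male germline, female germline and eggshell, accessory gland, chemosensory receptor and odorant-binding, cuticle protein, digestive protease, salivary glue and larval secreted, cytochrome P450, homeobox and Polycomb target, nuclear lamina and envelope, histone deacetylase and heterochromatin, heat shock and stress, and cytoskeleton and adhesion genes. Lists with at least 5 measured members were tested with cameraPR of limma (preset correlation between genes 0.01), adjusted over the lists of a fit, and with camera and a correlation estimated per list. The test with an estimated correlation also has only the residual degrees of freedom of the fit. Sets of genes called in another experiment were tested the same way. Adjacent pairs of called genes were counted along each chromosome arm and compared with 10000 permutations of the calls within arms, also for neighbours within 20 kb. The seed was 1.

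In each comparison the genes named are up to 10 higher and up to 10 lower genes with the largest absolute log2 among those with an adjusted p under 0.05, a single symbol and the same sign on every array that measures the contrast directly, then up to 4 members per list with an adjusted p under 0.05, and EcR, Eip74EF, Eip75B, br, Eip71CD (now MsrA) and Lam whatever their values. Eip74EF, Eip75B and Lam were not among the genes tested, nor was EcR in the fits of untreated Lam. Not all members named by the list part of the rule are given in the text. Groups, comparisons, lists, this rule and most alternatives were fixed before the data were examined. The alternatives tried were values as deposited without centring, no dye term, only rows with a value on every array, rows tested singly, each array left out, arrays scaled to the same spread, other selections of arrays or controls, stricter calls (adjusted p under 0.01, or a log2 of at least 0.5), and 100 genes per direction for the mRNA sets. The turned arrays, the neighbours more than 20 kb apart and the difference between the 2 TSA effects, with its alternatives, were added after the data were seen.

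The fits were tested on simulated data with the spread of the real arrays, a dye effect on every gene and 200 changed genes. Across comparisons, 1.49 to 83.6% of genes changed by a log2 of 0.5 were recovered, 7.46 to 100% at a log2 of 1 and 83.3 to 100% at a log2 of 2, the lowest shares at 1 and 2 being those of the ecdysone effect on Lam binding. The spread of that fit includes arrays of opposite sign. In 20 simulations per comparison, with each gene's variance as estimated, on average 8.69% of the calls were unchanged genes for Lam, 8.65% for Lam delta CaaX, 5.72% for their difference, 5.43% and 4.99% for the ecdysone effects on Lam and Dam, 5.63%, 7.42% and 5.85% for the TSA effects on Lam, Lam delta CaaX and Dam, and 6.97% for mRNA. With variances drawn from the fitted prior these means lay between 4.01% and 5.83%. A list raised by a log2 of 0.5 was called in each comparison, with 0 other lists called except 1 each for Lam delta CaaX, its difference from Lam and the TSA effect on Lam. The number of neighbouring pairs was close to its permuted mean for calls placed at random and far above it for calls placed in runs of 5.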

Results

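Lamin (Lam) binding and transcript levels were measured in Kc167 cells, an embryonic cell line of Drosophila melanogaster, on 35 two-colour cDNA arrays in 13 groups. In DamID, a protein fused to the E. coli adenine methyltransferase Dam marks DNA near the places it binds, and the methylated DNA is compared with that of cells expressing Dam alone. A value above 0 therefore means more methylation with the fusion protein than with Dam. Dam-Lam over Dam was measured on 4 arrays and Dam-Lam delta CaaX over Dam on 4 arrays, the second protein lacking the last 4 amino acids of Lam, which hold its membrane-targeting CaaX signal. The ecdysone experiment had 10 DamID arrays, 3 for Dam-Lam over Dam with the hormone, 3 without it, 2 for Dam-Lam with over without and 2 for Dam with over without (1 µM, 24 h). The experiment with trichostatin A (TSA), an inhibitor of histone deacetylases, had 10 DamID arrays in 5 dye-swapped pairs (100 nM, 24 h). Transcripts with over without ecdysone were measured on 5 arrays and mRNA over genomic DNA on 2 arrays.

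Values were present for 7542 probe rows on each array of the ecdysone and TSA experiments, 8231 to 8477 on the Dam-Lam arrays, 8450 to 8469 on the Dam-Lam delta CaaX arrays and 8485 on each array of mRNA over genomic DNA. Array medians as deposited lay between -0.22 and 0.14. The values are ratios on a log scale whose base the labels do not state. It was taken as log2, because the largest value, 11.6, is above the natural logarithm of a 16-bit ceiling, 11.1. Centring and direction are not stated either. Of 9006 probe rows, 7843 name 1 gene, 246 name several and 917 are not in the probe table. Rows of the same gene were averaged, and the counts of genes below include rows without a single gene name. Numbers after a gene are log2 ratios ± SE. The labels do not say whether arrays of a group came from separate cultures, so the p-values measure a spread between arrays that may be technical in origin.

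In untreated cells, Dam-Lam over Dam ratios were higher at 10 of 17 muscle genes, 20 of 56 cuticle protein genes and 13 of 25 neuronal genes, and lower at 11 of 19 nuclear lamina and envelope genes. All 4 lists passed camera, but with an estimated correlation their adjusted p was 0.352. Among the highest single genes (n = 4 arrays) was sls, which encodes a giant titin-like muscle protein (2.28 ± 0.40). Rbfox1, an RNA-binding splicing regulator, stood at 2.25 ± 0.15, PH4alphaPV, a prolyl 4-hydroxylase subunit, at 2.31 ± 0.16 and rg, an A-kinase anchor protein, at 2.19 ± 0.19. The other highest genes were CG10750 (2.71 ± 0.51), CG11227 (2.25 ± 0.14), Ktch (2.21 ± 0.16), wa-cup (2.20 ± 0.14), CG6614 (2.18 ± 0.16) and CG13539 (2.11 ± 0.22). The lowest ratios were those of CG7029 (-3.18 ± 0.45, 3 arrays), Ndg, the basement membrane protein nidogen (-2.46 ± 0.14), and rsh (-2.28 ± 0.14). Parp1, a poly(ADP-ribose) polymerase, had -2.28 ± 0.61, followed by CG3817 (-1.75 ± 0.14) and CG3281 (-1.60 ± 0.39). Cht10, a chitinase (-1.51 ± 0.13), fh, frataxin (-1.50 ± 0.30, 3 arrays), Elys, a nucleoporin (-1.47 ± 0.16), and CG2519 (-1.47 ± 0.14) came next. Array 2945 lay far from the other 3 for CG10750 (5.69), sls (4.24) and Parp1 (-5.85). Of the ecdysone-induced genes given whatever their values, the transcription factor gene br stood at 0.22 ± 0.14 (adjusted p = 0.245) and MsrA, listed under its older name Eip71CD, at 0.07 ± 0.14 (adjusted p = 0.699).

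By limma's moderated test, 1637 of 8062 genes were higher and 1204 lower with Dam-Lam than with Dam (adjusted p under 0.05), 515 and 103 of them by at least 2-fold. The count depends on single arrays. Without array 2907, 219 were higher and 28 lower, without array 2921, 7 and 4, and without array 2955 2031 were lower. With 3 arrays and a dye term, the spread comes from the remaining pair in the same dye. That pair is 2945 and 2955 (r = 0.51) without 2907 or 2921, and 2907 and 2921 (r = 0.76) without 2945 or 2955. The counts therefore do not show which array carries the signal. With the 3 untreated Dam-Lam over Dam arrays of the ecdysone experiment added as deposited, limma called 0 higher and 0 lower (215 at an unadjusted p under 0.05), and with 2 of those 3 arrays turned round, a choice made after the values were seen, 1669 and 1504.

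Several gene lists differed from the remaining genes in their Lam ratios. Of cytochrome P450 genes, which encode detoxification and hormone-modifying enzymes, 25 of 49 were higher, 1 lower and 23 neither, or 27 and 2 adjusted over the list alone (camera adjusted p = 3.61e-06, adjusted p = 0.352 with an estimated correlation). Cyp28a5 (1.92 ± 0.14), Cyp6a18 (1.74 ± 0.15) and Cyp9b1 (1.52 ± 0.13) were highest. Among neuronal genes, 13 of 25 were higher, 0 lower and 12 neither, or 13 and 0 adjusted over the list alone (camera adjusted p = 0.00261, adjusted p = 0.352 with an estimated correlation). They include Rim, an active zone protein (1.28 ± 0.14), Ace, acetylcholinesterase (1.24 ± 0.15), and the adhesion molecule Dscam1 (1.23 ± 0.16). In the cuticle list, 20 of 56 were higher, 0 lower and 36 neither, or 20 and 0 adjusted over the list alone (camera adjusted p = 0.00416, adjusted p = 0.352 with an estimated correlation). TwdlH (1.77 ± 0.36), TwdlL (1.27 ± 0.21) and TwdlB (1.24 ± 0.14) were at its top. Of homeobox and Polycomb target genes, 14 of 34 were higher, 2 lower and 18 neither, or 14 and 2 adjusted over the list alone (camera adjusted p = 0.0104, adjusted p = 0.354 with an estimated correlation). Examples are knrl (1.46 ± 0.20), al (1.43 ± 0.24) and gsb-n (1.22 ± 0.15). For muscle genes, 10 of 17 were higher, 0 lower and 7 neither, or 10 and 1 adjusted over the list alone (camera adjusted p = 0.0235, adjusted p = 0.352 with an estimated correlation). Besides sls they include bt, the twitchin-like projectin (1.56 ± 0.14), and the actin gene Act79B (0.92 ± 0.15). Among fat body and yolk genes, 7 of 12 were higher, 0 lower and 5 neither, or 8 and 1 adjusted over the list alone (camera adjusted p = 0.0450, adjusted p = 0.405 with an estimated correlation). The yolk protein gene Yp2 (0.89 ± 0.17, 3 arrays) and the lipoprotein gene apolpp (0.93 ± 0.15) were among the higher ones. In the list of salivary glue and larval secreted genes, 5 of 12 were higher, 0 lower and 7 neither, or 6 and 0 adjusted over the list alone (camera adjusted p = 0.0470, adjusted p = 0.361 with an estimated correlation), for example Eig71Ee (0.84 ± 0.15).

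The opposite was seen among nuclear lamina and envelope genes, of which 1 of 19 was higher, 11 lower and 7 neither, or 2 and 11 adjusted over the list alone (camera adjusted p = 0.0104, adjusted p = 0.352 with an estimated correlation). The nucleoporin genes Nup358 (-0.91 ± 0.14), Nup153 (-0.84 ± 0.16) and Nup205 (-0.73 ± 0.18) were among the lower members. For oxidative phosphorylation genes, 4 of 57 were higher, 11 lower and 42 neither, or 2 and 6 adjusted over the list alone (camera adjusted p = 0.0104, adjusted p = 0.405 with an estimated correlation). The lower members include ND-B14.7 (-1.03 ± 0.30), while SdhAL (0.93 ± 0.15) and ND-B14.5AL (0.92 ± 0.18), paralogues of respiratory chain subunits, were higher.

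The remaining lists did not pass camera at an adjusted p under 0.05. In the proteasome list, matched by symbol pattern, 7 of 32 measured genes were higher and 5 lower (7 and 5 adjusted over the list alone, camera adjusted p = 0.640). Its highest members were the paralogues Prosbeta4R2 (1.59 ± 0.20), Prosbeta4R1 (1.33 ± 0.18), Rpn13R (1.32 ± 0.14) and Prosalpha4T2 (1.17 ± 0.16). Its median was -0.23 and its mean 0.01, and the pattern also caught Prosap, which is not a proteasome gene. Elsewhere, 9 of 22 ecdysone response genes were higher and 1 lower (10 and 2 adjusted over the list alone, camera adjusted p = 0.0884). 14 of 42 male germline genes were higher and 6 lower (14 and 6 adjusted over the list alone, camera adjusted p = 0.0792), and 6 of 20 digestive protease genes were higher and 0 lower (10 and 0 adjusted over the list alone, camera adjusted p = 0.0884). For housekeeping functions, 3 of 30 ribosomal protein genes were higher and 6 lower (3 and 6 adjusted over the list alone, camera adjusted p = 0.0848), and 1 of 28 cell cycle and replication genes was higher and 7 lower (1 and 7 adjusted over the list alone, camera adjusted p = 0.0884). 1 of 23 histone deacetylase and heterochromatin genes was higher and 5 lower (1 and 5 adjusted over the list alone, camera adjusted p = 0.0957). 5 of 20 immune response genes were higher and 2 lower (5 and 2 adjusted over the list alone, camera adjusted p = 0.253), and 8 of 19 hemocyte genes were higher and 3 lower (8 and 3 adjusted over the list alone, camera adjusted p = 0.536). 4 of 18 chemosensory receptor and odorant-binding genes were higher and 1 lower (4 and 0 adjusted over the list alone, camera adjusted p = 0.282), and 3 of 12 cytoskeleton and adhesion genes were higher and 0 lower (3 and 0 adjusted over the list alone, camera adjusted p = 0.477). 1 of 16 heat shock and stress genes was higher and 2 lower (0 and 1 adjusted over the list alone, camera adjusted p = 0.610), and 3 of 16 female germline and eggshell genes were higher and 1 lower (3 and 1 adjusted over the list alone, camera adjusted p = 0.789). 2 of 7 cell death genes were higher and 0 lower (1 and 0 adjusted over the list alone, camera adjusted p = 0.792), and 1 of 6 accessory gland genes was higher and 0 lower (1 and 0 adjusted over the list alone, camera adjusted p = 0.640). Last, 0 of 6 ecdysteroid synthesis genes were higher and 0 lower (0 and 0 adjusted over the list alone, camera adjusted p = 0.891), with a median of -0.06 and a mean of 0.03. With an estimated correlation, the adjusted p of these lists lay between 0.352 and 0.857. Symbol patterns placed Orcokinin, a neuropeptide gene, in the chemosensory list and Acph-1, an acid phosphatase gene, in the accessory gland list.

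**Figure D1:**
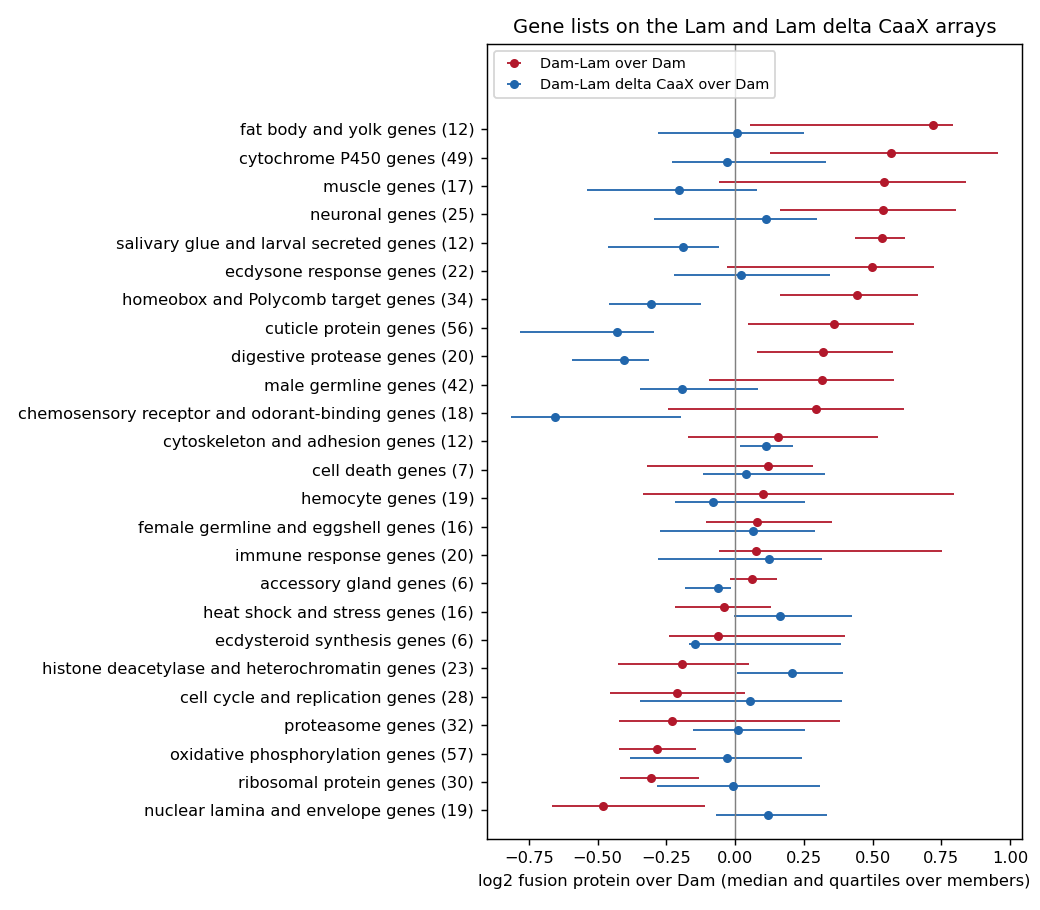
Median log2 ratio over Dam (points) and quartiles (lines) of the measured members of each gene list, for Dam-Lam in red and Dam-Lam delta CaaX in blue, with the number of members on the Dam-Lam arrays in brackets. The median of the cuticle list is 0.36 with Dam-Lam and -0.43 with Dam-Lam delta CaaX.

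Dam-Lam delta CaaX gave another picture, with few large ratios above 0 and a group of very low ones. The highest genes (n = 4 arrays) were Sec8, an exocyst subunit (1.40 ± 0.35), PpD6 (1.38 ± 0.14), stck, a focal adhesion protein (1.25 ± 0.14), and CG15706 (1.25 ± 0.12) and CG32066 (1.21 ± 0.13). LKRSDH, a lysine-degrading enzyme (1.20 ± 0.17), Nna1 (1.16 ± 0.25), CG11226 (1.11 ± 0.12), the arrestin gene krz (1.11 ± 0.15) and CG7514 (1.11 ± 0.16) followed. The lowest were Ndg (-3.67 ± 0.14), ATPsynC, a membrane subunit of the mitochondrial ATP synthase (-3.63 ± 0.14), and CG30457 (-3.50 ± 0.12), rsh (-3.46 ± 0.13) and pigeon (-3.26 ± 0.13). Spt3, a subunit of the SAGA coactivator, had -3.14 ± 0.14 and mRpL37, a mitochondrial ribosomal protein, -2.49 ± 0.15, with CG3281 (-2.96 ± 0.12), spab (-2.91 ± 0.13) and CG3104 (-2.81 ± 0.12) between them. The ecdysone receptor gene EcR had a ratio of 0.66 ± 0.12 (adjusted p = 0.00591) and br one of 0.52 ± 0.13 (adjusted p = 0.0182), with MsrA at 0.34 ± 0.12 (adjusted p = 0.0524).

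Of 8056 genes, limma called 1298 higher and 1318 lower, of which 38 and 110 by at least 2-fold. Without array 2967 the counts were 498 and 631, and without array 2968 476 and 551. The spread then came from arrays 2962 and 2966, the remaining pair in the same dye. In the cuticle list, 2 of 56 were higher, 31 lower and 23 neither, or 3 and 38 adjusted over the list alone (camera adjusted p = 7.03e-09, adjusted p = 0.639 with an estimated correlation). The lower members include Cpr47Ee (-1.24 ± 0.20), Cpr47Eb (-1.12 ± 0.13), TwdlD (-1.12 ± 0.13) and TwdlN (-1.06 ± 0.13). Among chemosensory receptor and odorant-binding genes, 0 of 18 were higher, 12 lower and 6 neither, or 0 and 12 adjusted over the list alone (camera adjusted p = 5.17e-06, adjusted p = 0.639 with an estimated correlation). The lowest were Obp44a (-1.64 ± 0.14), Obp99c (-1.08 ± 0.13), Ir47a (-0.90 ± 0.12) and Obp83g (-0.88 ± 0.13). For digestive protease genes, 2 of 19 were higher, 11 lower and 6 neither, or 2 and 14 adjusted over the list alone (camera adjusted p = 0.00217, adjusted p = 0.639 with an estimated correlation), Jon25Bii (-0.86 ± 0.13) and Jon25Bi (-0.81 ± 0.13) being among the lower ones. Of homeobox and Polycomb target genes, 0 of 34 were higher, 11 lower and 23 neither, or 0 and 11 adjusted over the list alone (camera adjusted p = 0.00729, adjusted p = 0.639 with an estimated correlation), for example Ptx1 (-1.18 ± 0.14) and hry (-0.72 ± 0.12). For muscle genes, 0 of 18 were higher, 5 lower and 13 neither, or 0 and 5 adjusted over the list alone (camera adjusted p = 0.0277, adjusted p = 0.720 with an estimated correlation). Mlc2, a myosin light chain (-2.12 ± 0.14), and Mlp60A (-0.81 ± 0.12) were among the lower members. Of histone deacetylase and heterochromatin genes, 6 of 20 were higher, 0 lower and 14 neither, or 7 and 1 adjusted over the list alone (camera adjusted p = 0.145, adjusted p = 0.761 with an estimated correlation), HDAC4 (0.97 ± 0.13) and HDAC1 (0.49 ± 0.12) being among the higher ones. In the cell cycle and replication list, 7 of 26 were higher, 3 lower and 16 neither, or 8 and 4 adjusted over the list alone (camera adjusted p = 0.864, adjusted p = 0.975 with an estimated correlation), the cyclin gene CycB being among the lower ones (-1.71 ± 0.16).

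Tested in 1 model of the 8 arrays, the ratio was higher with Lam than with Lam delta CaaX at 1626 of 7711 genes and lower at 1089. The proteins were never together on an array, so their difference cannot be told apart from another difference between the sets of arrays. The largest difference was that of Alk, a receptor tyrosine kinase (3.48 ± 0.28). ATPsynC (3.26 ± 0.22), CG10750 (3.12 ± 0.65), pigeon (3.02 ± 0.32) and CG7406 (2.91 ± 0.43) came next, followed by sls (2.83 ± 0.48), CG30457 (2.81 ± 0.21), TwdlH (2.74 ± 0.42), Spn100A (2.72 ± 0.34) and dpr8 (2.66 ± 0.37). The low untreated Lam delta CaaX ratios of Alk, ATPsynC and pigeon were not seen in the TSA experiment. There, Lam delta CaaX over Dam with TSA was -0.22, -0.82 and -0.38, and its own change with TSA 0.23, -0.59 and 0.30. Dam changed by 0.13, 0.18 and 0.51. The low ratio of CG30457 was seen there too (-1.34, 0.925 and -0.11). The lowest differences were those of MED1, a Mediator subunit (-3.10 ± 0.87, 6 arrays), snama (-2.55 ± 0.80), Sec8 (-2.22 ± 0.51) and fh (-1.95 ± 0.33, 7 arrays), before Unr (-1.85 ± 0.61), CG10646 (-1.69 ± 0.30) and Snrk (-1.63 ± 0.20). The Hedgehog co-receptor gene ihog (-1.62 ± 0.29), milt, which encodes a kinesin adaptor (-1.62 ± 0.23), and Grip128, of the gamma-tubulin ring complex (-1.56 ± 0.28), were lower too. The lower count fell to 633 without array 2921, 661 without array 2967 and 649 without array 2968. The differences at br (-0.30 ± 0.21) and MsrA (-0.27 ± 0.18) did not pass.

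The lists that differed between the proteins were led by cuticle genes, of which 35 of 55 were higher, 0 lower and 20 neither, or 37 and 0 adjusted over the list alone (camera adjusted p = 6.39e-10, adjusted p = 0.0866 with an estimated correlation). In the homeobox list, 18 of 34 were higher, 1 lower and 15 neither, or 21 and 1 adjusted over the list alone (camera adjusted p = 6.45e-05, adjusted p = 0.0944 with an estimated correlation). For P450 genes, 22 of 46 were higher, 1 lower and 23 neither, or 22 and 3 adjusted over the list alone (camera adjusted p = 8.84e-05, adjusted p = 0.0866 with an estimated correlation), Cyp9b1 (2.07 ± 0.18) being highest. Among chemosensory genes, 12 of 18 were higher, 0 lower and 6 neither, or 12 and 0 adjusted over the list alone (camera adjusted p = 2.24e-04, adjusted p = 0.0866 with an estimated correlation). For digestive proteases, 10 of 19 were higher, 0 lower and 9 neither, or 10 and 0 adjusted over the list alone (camera adjusted p = 0.00147, adjusted p = 0.130 with an estimated correlation). Neuronal genes include Dscam1 (2.10 ± 0.24), and 11 of 25 were higher, 0 lower and 14 neither, or 11 and 1 adjusted over the list alone (camera adjusted p = 0.00182, adjusted p = 0.0866 with an estimated correlation). For muscle genes, 9 of 17 were higher, 0 lower and 8 neither, or 9 and 0 adjusted over the list alone (camera adjusted p = 0.00182, adjusted p = 0.0866 with an estimated correlation).

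Further down came the glue and larval secreted list, in which 6 of 12 were higher, 0 lower and 6 neither, or 9 and 0 adjusted over the list alone (camera adjusted p = 0.0126, adjusted p = 0.133 with an estimated correlation). For male germline genes, 14 of 40 were higher, 1 lower and 25 neither, or 14 and 1 adjusted over the list alone (camera adjusted p = 0.0273, adjusted p = 0.112 with an estimated correlation), wa-cup (2.44 ± 0.18) being highest. For fat body and yolk genes, 7 of 12 were higher, 1 lower and 4 neither, or 7 and 1 adjusted over the list alone (camera adjusted p = 0.0490, adjusted p = 0.230 with an estimated correlation). The opposite direction was seen for nuclear lamina and envelope genes, where 0 of 19 were higher, 5 lower and 14 neither, or 0 and 12 adjusted over the list alone (camera adjusted p = 0.00349, adjusted p = 0.133 with an estimated correlation). Examples are Nup133 (-1.28 ± 0.22) and Nup358 (-0.83 ± 0.21). Of histone deacetylase and heterochromatin genes, 0 of 20 were higher, 7 lower and 13 neither, or 0 and 11 adjusted over the list alone (camera adjusted p = 0.0116, adjusted p = 0.130 with an estimated correlation), among them the Polycomb group gene Scm (-1.27 ± 0.25).

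Of 7707 genes tested with both proteins, 216 were higher with both (247.62 for independent lists of these sizes), 231 were lower with both (178.63), 361 were higher with Lam and lower with Lam delta CaaX (262.5) and 61 the reverse (168.5). Across 7432 genes, which are not independent replicates, the profiles correlated at r = 0.01 in untreated cells, and with TSA at 0.59 across 7089 genes, in both cases without an array in common. With TSA both profiles are taken over Dam of treated cells, the same DNA sample in the model. A trait of that reference can raise r, so 0.59 does not show that the proteins became more alike.

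Genes higher with Lam had low transcript levels in these cells. On the 2 arrays of mRNA over genomic DNA (3458 and 3459), their median log2 level lay -1.30 and -1.98 from that of the other measured genes, a mean of -1.64 (SD 0.483, n = 2). None of 10000 random gene sets of this size lay as far away. With genes in 10 equal groups by mRNA level, 49.1% were higher with Lam in the lowest group, against 4.46% in the highest. Genes higher with Lam delta CaaX lay 0.77 and 0.89 above the others, and their share went from 4.79% in the lowest group to 27.7% in the highest. Across genes, which are not independent replicates, Spearman's rho between mRNA level and ratio was -0.38 and -0.42 for Lam and 0.28 and 0.29 for Lam delta CaaX.

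**Figure D2:**
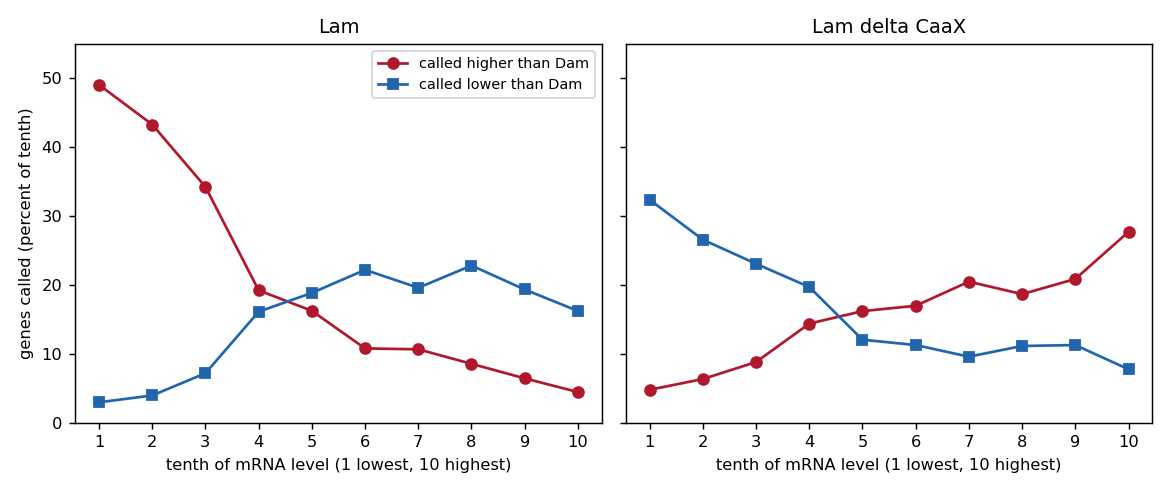
Percent of genes called higher (red) or lower (blue) than Dam alone, in 10 equal groups by mRNA level from lowest (1) to highest (10), for Lam on the left and Lam delta CaaX on the right. The higher share goes from 49.1% to 4.46% for Lam and from 4.79% to 27.7% for Lam delta CaaX.

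Genes higher with Lam lay next to each other. Among 6849 genes ordered by the reference table, 648 adjacent pairs were both higher, against a mean of 281.11 (234 to 331) when the calls were permuted within chromosome arms (two-sided permutation p = 0.0002, the smallest that 10000 permutations can give). The pairs formed 80 runs of 4 or more genes. The longest held 12 genes, 1 run on 2R from CG9876 to Prosbeta5R1, with Klp59C, Gpdh2 and RpL22-like inside it, and 1 on 3L from CG32379 to Pura, with Cyp4d8, lqf and frac inside it. These genes were named after the values were seen. Pairs whose starts lie more than 20 kb apart numbered 288 against a permuted mean of 68.4, and pairs within 20 kb 360 against 212.74. For genes higher with Lam delta CaaX there were 244 adjacent pairs against 171.13 (119 to 219, permutation p = 0.0002). Gene order comes from the current reference annotation (Release 6), by gene number, since the probe table gives no positions.

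With TSA, genes higher with Lam in untreated cells lost ratio. PH4alphaPV fell by 1.47 ± 0.17, bt by 1.35 ± 0.14, wa-cup by 1.05 ± 0.15, Cyp28a5 by 1.02 ± 0.15 and sls by 0.95 ± 0.14. The largest decreases were those of elfless (-1.61 ± 0.25), CG15450 (-1.60 ± 0.14), the scavenger receptor gene ninaD (-1.53 ± 0.16), and CG10752 (-1.51 ± 0.28), CG7329 (-1.49 ± 0.13) and CG13700 (-1.48 ± 0.25). CG9284 (-1.46 ± 0.23), Cdlc2, a dynein light chain gene (-1.46 ± 0.21), and CG4686 (-1.46 ± 0.32) followed. The largest increases were those of SMC6, of the SMC5/6 complex (2.17 ± 0.54), mRpL37 (1.72 ± 0.41), r2d2, of the RNA interference pathway (1.41 ± 0.21), and CG3803 (1.41 ± 0.17), CG16812 (1.34 ± 0.21) and CG17896 (1.27 ± 0.24). Polr3A, a subunit of RNA polymerase III (1.26 ± 0.16), CG14339 (1.24 ± 0.13), CG9822 (1.24 ± 0.16) and tefu, the ATM kinase gene (1.17 ± 0.14), rose as well. These are changes of Dam-Lam minus changes of Dam, from 1 model of the 10 arrays, in which each difference rests on a dye-swapped pair.

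Of the 1345 Lam-higher genes measured, 703 fell and 8 rose with TSA, with a median change of -0.47 (camera p = 4.61e-41, p = 6.68e-04 with an estimated correlation). Of 1025 Lam-lower genes, 395 rose and 9 fell, with a median of 0.35 (camera p = 4.79e-28, p = 1.03e-04 with an estimated correlation). In all, 879 of 7089 genes rose and 1247 fell. Without array 3686, 219 and 497 were called, without array 3687, 360 and 643, and without array 3690, 530 and 824. Set against the 4 untreated Dam-Lam arrays of the separate experiment in place of the direct arrays, limma called 0 in either direction (1137 at an unadjusted p under 0.05). For P450 genes, 1 of 43 was higher, 17 lower and 25 neither, or 1 and 19 adjusted over the list alone (camera adjusted p = 0.0444, adjusted p = 0.469 with an estimated correlation). For digestive proteases, 0 of 18 were higher, 7 lower and 11 neither, or 0 and 9 adjusted over the list alone (camera adjusted p = 0.0444, adjusted p = 0.469 with an estimated correlation), including Jon99Ci (-0.90 ± 0.15) and Ser6 (-0.86 ± 0.15). Of nuclear lamina and envelope genes, 3 of 19 were higher, 3 lower and 13 neither, or 3 and 3 adjusted over the list alone (camera adjusted p = 0.154, adjusted p = 0.469 with an estimated correlation), the higher ones including Nup358 (0.90 ± 0.14) and Nup153 (0.79 ± 0.13). Of histone deacetylase and heterochromatin genes, 6 of 20 were higher, 2 lower and 12 neither, or 7 and 2 adjusted over the list alone (camera adjusted p = 0.259, adjusted p = 0.469 with an estimated correlation), HDAC1, which encodes a target of TSA, being among the lower ones (-0.80 ± 0.14). EcR (0.25 ± 0.14), br (0.02 ± 0.14) and MsrA (-0.16 ± 0.13) did not pass.

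**Figure D3:**
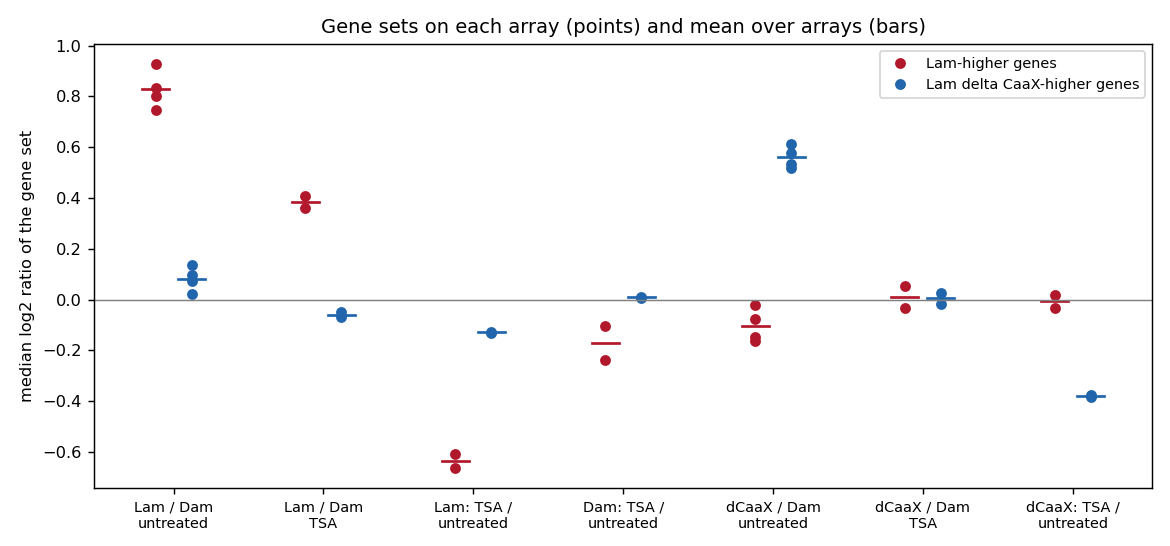
Median log2 ratio of genes higher with Lam (red) and with Lam delta CaaX (blue) on each array (points), with the mean over arrays (bars), for untreated, TSA-treated and direct treated over untreated comparisons. Lam-higher genes have a median of 0.82 over the 4 untreated Dam-Lam arrays and 0.39 over the 2 arrays with TSA.

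The Lam delta CaaX ratio changed as well, in part at the same genes. Increases were largest at rsh (2.26 ± 0.23) and Ndg (2.22 ± 0.20), which were among the lowest in untreated cells, followed by SMC6 (1.70 ± 0.54), Aatf (1.47 ± 0.20), CG14339 (1.47 ± 0.13) and CG9822 (1.45 ± 0.16). Spt3 (1.42 ± 0.21), CG13311 (1.40 ± 0.19), CG16812 (1.40 ± 0.21) and ND-B22, of respiratory complex I (1.40 ± 0.15), rose by less. Decreases were largest at CG9205 (-2.23 ± 0.60), e(r) (-1.88 ± 0.13), peg (-1.60 ± 0.25), CG6912 (-1.54 ± 0.15) and CG32772 (-1.48 ± 0.16), with Cyp6v1 (-1.48 ± 0.38), Tina-1 (-1.47 ± 0.14), CG15861 (-1.44 ± 0.14), nes (-1.44 ± 0.20) and CG32147 (-1.43 ± 0.16) after them. In all, 1146 of 7089 genes rose and 1443 fell. Without array 3692 the counts were 500 and 695, without array 3693 399 and 713, and against the 4 arrays of the separate experiment 88 and 125, of which 171 were called the same way in both and 1, ATPsynC, the opposite way. Of 1114 Lam delta CaaX-higher genes, 559 fell and 21 rose, with a median of -0.42 (camera p = 2.19e-25, p = 2.74e-04 with an estimated correlation), and of 1072 lower genes 408 rose and 31 fell, with a median of 0.32.

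In the heat shock and stress list, 0 of 15 were higher, 8 lower and 7 neither, or 0 and 10 adjusted over the list alone (camera adjusted p = 0.00165, adjusted p = 0.397 with an estimated correlation). They include the glutathione transferase gene GstD1 (-1.07 ± 0.14), the superoxide dismutase gene Sod2 (-0.96 ± 0.18) and the small heat shock gene Hsp27 (-0.92 ± 0.13). For cuticle genes, 16 of 48 were higher, 3 lower and 29 neither, or 16 and 3 adjusted over the list alone (camera adjusted p = 0.00165, adjusted p = 0.397 with an estimated correlation), with Cpr56F (1.13 ± 0.14) and Cpr64Ad (1.04 ± 0.15) highest. For homeobox and Polycomb target genes, 8 of 30 were higher, 1 lower and 21 neither, or 7 and 0 adjusted over the list alone (camera adjusted p = 0.0281, adjusted p = 0.659 with an estimated correlation), for example pdm2 (0.86 ± 0.16) and inv (0.75 ± 0.15). MsrA fell (-0.71 ± 0.13), while EcR (0.10 ± 0.14) and br (-0.37 ± 0.14) did not pass.

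A direct test of the difference between the 2 TSA changes, chosen after the values were seen, called 1342 genes higher and 1354 lower for Lam than for Lam delta CaaX. Lam-higher genes had a median difference of -0.60 (848 lower, 16 higher, camera p = 2.51e-64, p = 2.93e-04 with an estimated correlation), and Lam delta CaaX-higher genes one of 0.30. Both profiles were flatter with TSA (slope of treated on untreated 0.364 for Lam and 0.0679 for Lam delta CaaX). The untreated profiles were nearly uncorrelated (r = 0.01). Genes picked as high with 1 protein then fall more for that protein, so these medians do not show a response beyond the flattening. The higher count was 848 without a dye term. Higher and lower counts were 277 and 846 without array 3692, 280 and 687 without array 3693, 277 and 722 without array 3686, and 466 and 863 without array 3687.

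Dam alone, the background of these ratios, changed as well. The gene gem fell by 1.92 ± 0.12, followed by CG8490 (-1.39 ± 0.10), CG6610 (-1.34 ± 0.12), CG10465 (-1.30 ± 0.09) and rush (-1.29 ± 0.14). jtb (-1.25 ± 0.10), CG12730 (-1.23 ± 0.10), CG32006 (-1.21 ± 0.11), Sec61beta, of the translocon (-1.19 ± 0.09), and fru, a transcription factor of the sex determination pathway (-1.19 ± 0.12), fell too. The largest increases were those of Flo1, flotillin (1.80 ± 0.40), CG5250 (1.35 ± 0.15), CG12375 (1.16 ± 0.11), CG31441 (1.16 ± 0.18) and CG1750 (1.11 ± 0.17), then CG14834 (1.11 ± 0.11), Ctns (0.98 ± 0.14), Mst87F (0.97 ± 0.14), CG10809 (0.94 ± 0.11) and Grx3 (0.92 ± 0.11). Of 7089 genes, 1107 rose and 1135 fell, or 356 and 546 without array 3690. For ribosomal protein genes, 1 of 28 was higher, 7 lower and 20 neither, or 1 and 7 adjusted over the list alone (camera adjusted p = 0.0118, adjusted p = 0.578 with an estimated correlation), RpLP2 (-1.12 ± 0.09) being lowest. For homeobox genes, 0 of 30 were higher, 11 lower and 19 neither, or 0 and 12 adjusted over the list alone (camera adjusted p = 0.0186, adjusted p = 0.604 with an estimated correlation). For neuronal genes, 1 of 25 was higher, 10 lower and 14 neither, or 1 and 12 adjusted over the list alone (camera adjusted p = 0.0236, adjusted p = 0.604 with an estimated correlation). Lam-higher genes had a median Dam change of -0.17. Dam methylation fell at MsrA (-0.65 ± 0.09) and rose at br (0.37 ± 0.10), with EcR at 0.09 ± 0.10.

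The TSA effects on Lam and on Lam delta CaaX are both taken against the same Dam arrays, which ties their chance values together. Across 7089 genes they correlated at r = 0.44, where unchanged groups simulated against shared Dam arrays gave 0.49, so r cannot tell a shared change from shared arrays. The covariance was 0.0866 against a simulated 0.0128, a difference of 0.0738. The simulation left Dam unchanged, whereas the change of Dam with TSA was called at 2242 of 7089 genes and is subtracted from both effects. The excess covariance can therefore not be read as a change shared by the 2 proteins. Both rose at 410 genes (142.1 for independent lists) and both fell at 500 (253.83), and part of the excess may come from the shared arrays or the subtracted Dam change. On the arrays of treated over untreated DNA, without subtracting Dam, the changes of the 2 proteins correlated at r = 0.67, and those of Dam-Lam and of Dam alone at 0.72.

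Ecdysone raised the transcripts of known hormone targets. Of the ecdysone response genes, 7 of 22 were higher, 0 lower and 15 neither, or 9 and 2 adjusted over the list alone (camera adjusted p = 4.20e-06, adjusted p = 0.440 with an estimated correlation). They include the nuclear receptor gene Hr3 (2.43 ± 0.27), ImpL2, a secreted insulin-binding protein (1.83 ± 0.17), the ABC transporter gene E23 (1.73 ± 0.21), vri, a bZIP transcription factor (1.23 ± 0.20), and MsrA (1.20 ± 0.16). EcR itself was at 0.47 ± 0.14 (adjusted p = 0.124) and br at -0.17 ± 0.13 (adjusted p = 0.605). The largest increases (n = 5 arrays) were those of Dtg (4.32 ± 0.18), NT5E-2, a 5′-nucleotidase (3.59 ± 0.32), CG14629 (3.42 ± 0.25), Hsp27 (3.40 ± 0.24), and CG6287 (3.26 ± 0.28) and Ama (3.21 ± 0.29). Pepck2, a phosphoenolpyruvate carboxykinase gene (2.93 ± 0.31), and blot (2.83 ± 0.19), Ugt317A1 (2.67 ± 0.33) and CG3961 (2.60 ± 0.33) came next. The largest decreases were those of Nplp2 (-2.58 ± 0.20), Gnmt, glycine N-methyltransferase (-2.50 ± 0.26), and CG15211 (-1.99 ± 0.19) and CG10512 (-1.64 ± 0.23). RpL23, a ribosomal protein (-1.62 ± 0.21), and Fmo-2 (-1.51 ± 0.18), CG6912 (-1.48 ± 0.22), Dbct (-1.36 ± 0.15), CG7720 (-1.36 ± 0.16) and CG3376 (-1.35 ± 0.24) also fell.

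For heat shock and stress genes, 2 of 15 were higher, 0 lower and 13 neither, or 4 and 1 adjusted over the list alone (camera adjusted p = 1.23e-05, adjusted p = 0.440 with an estimated correlation), the higher ones being Hsp27 and the catalase gene Cat (1.31 ± 0.13). Among oxidative phosphorylation genes, 0 of 50 were higher, 0 lower and 50 neither, or 0 and 0 adjusted over the list alone (camera adjusted p = 2.82e-04, adjusted p = 0.440 with an estimated correlation), their median being -0.24. Of P450 genes, 4 of 43 were higher, 3 lower and 36 neither, or 4 and 3 adjusted over the list alone (camera adjusted p = 0.253, adjusted p = 0.755 with an estimated correlation), the higher ones including Cyp6a8 (1.92 ± 0.21) and Cyp6a18 (1.83 ± 0.29). Of hemocyte genes, 2 of 16 were higher, 1 lower and 13 neither, or 4 and 1 adjusted over the list alone (camera adjusted p = 0.171, adjusted p = 0.440 with an estimated correlation), the phagocytosis receptor gene eater (1.52 ± 0.25) being among the higher ones. Of cell death genes, 1 of 7 was higher, 0 lower and 6 neither, or 2 and 0 adjusted over the list alone (camera adjusted p = 0.171, adjusted p = 0.440 with an estimated correlation), the higher one being Dronc, an initiator caspase (1.03 ± 0.16). In all, 154 of 7089 transcripts rose and 114 fell. Array 3427 stood apart from the others, with a correlation across genes of -0.14 with array 3426. Without it 353 rose and 456 fell. Without array 3426 the counts were 63 and 29, without 3450 75 and 38, without 3451 55 and 29, and without 3452 98 and 59.

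**Figure D4:**
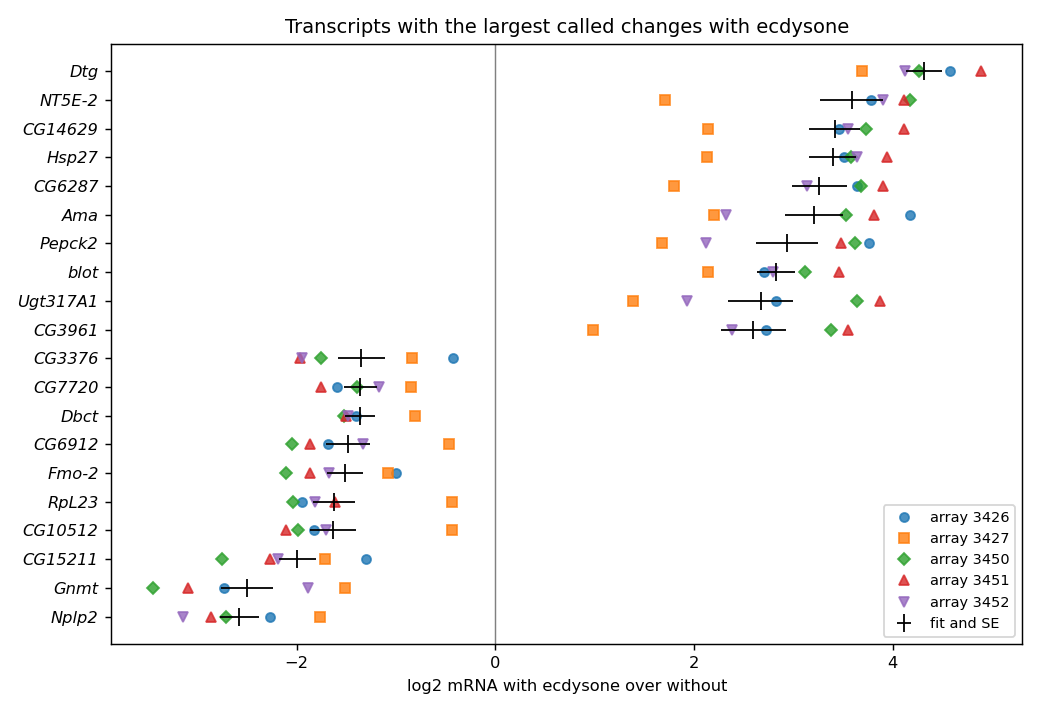
Log2 mRNA with over without ecdysone on each of the 5 arrays (symbols) and the fitted value with its SE (black) for the 10 largest increases and 10 largest decreases. Array 3427 lies closest to 0 for NT5E-2 (1.71), Hsp27 (2.14) and RpL23 (-0.44).

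No gene passed the test for a change of Lam binding with ecdysone, including the hormone's own targets. The change at EcR was -0.03 ± 0.21 (adjusted p = 0.973), at br -0.06 ± 0.20 and at MsrA 0.07 ± 0.28. The changes of Dam alone were -0.11 ± 0.20, 0.22 ± 0.18 and -0.32 ± 0.27. With limma, 0 of 7089 genes were higher and 0 lower for Lam (247 at an unadjusted p under 0.05, where chance gives 354.45), and 0 and 0 for Dam (83). In simulated data of this design, 7.46% of genes changed by a log2 of 1 were recovered for Lam.

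The direction of the 6 Dam-Lam over Dam arrays in this experiment is unsettled. Arrays 3428, 3441 and 3443 correlate with the separate Lam profile at r = -0.58, -0.74 and -0.74 across genes, and arrays 3434, 3436 and 3442 at 0.53, 0.80 and 0.73. Arrays of the same group with Dam-Lam in the same dye correlate at -0.64 with ecdysone and -0.56 without it. The 2 dye-swapped arrays of Dam-Lam with over without ecdysone correlate at 0.017 and the 2 of Dam at 0.064, so their agreement does not settle their direction either. With the 3 negative arrays turned round, chosen after the values were seen, limma called 0 genes higher and 0 lower for Lam (1001 at an unadjusted p under 0.05) and 0 and 0 for Dam (331). The changes for Lam then were -0.14 ± 0.21 at EcR, -0.05 ± 0.17 at br and -0.29 ± 0.21 at MsrA, and those for Dam -0.05 ± 0.19, 0.22 ± 0.16 and -0.14 ± 0.20. With every Cy3 array turned, as if values were Cy5 over Cy3, 0 and 0 were called for Lam (31) and for Dam (18), and the changes were 0.17 ± 0.21, -0.05 ± 0.23 and -0.15 ± 0.28 for Lam and -0.02 ± 0.20, -0.10 ± 0.21 and 0.27 ± 0.26 for Dam.

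As deposited, 3 lists passed camera for Lam. They were cuticle genes (median 0.20, camera adjusted p = 4.06e-04), digestive proteases (median 0.30, camera adjusted p = 0.0150) and P450 genes (median 0.20, camera adjusted p = 0.0272), each with an adjusted p = 0.637 with an estimated correlation. Of their 48, 18 and 43 measured members, 0 were called singly, also 0 adjusted over the list alone. With the 3 arrays turned, cuticle genes (median 0.23, camera adjusted p = 0.0302) and P450 genes (median -0.13, camera adjusted p = 0.0302) passed, the second downward, and proteases did not (median 0.19, camera adjusted p = 0.0794). With every Cy3 array turned none of the 3 passed (cuticle median 0.03, camera adjusted p = 0.733, proteases median 0.09, camera adjusted p = 0.733, P450 median 0.09, camera adjusted p = 0.426), and homeobox genes passed (median 0.21, camera adjusted p = 0.0149).

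For Dam, 5 lists passed as deposited. They were cuticle genes (median -0.19, camera adjusted p = 0.00120), chemosensory genes (median -0.26, camera adjusted p = 0.00831), accessory gland genes (median -0.30, camera adjusted p = 0.0130), digestive proteases (median -0.23, camera adjusted p = 0.0244) and ecdysone response genes (median -0.19, camera adjusted p = 0.0499), with an adjusted p = 0.436 with an estimated correlation, or 0.698 for proteases. Of their 48, 14, 5, 18 and 22 members, 0 were called singly, also 0 adjusted over the list alone. With the 3 arrays turned, the medians were -0.15 for cuticle genes (camera adjusted p = 0.00435), -0.23 for chemosensory genes (0.00105), -0.33 for accessory gland genes (0.0548), -0.17 for proteases (0.0313) and -0.0022 for ecdysone response genes (0.881). Ribosomal protein (median -0.15, camera adjusted p = 0.0243) and oxidative phosphorylation genes (median -0.13, camera adjusted p = 0.0243) then passed. With every Cy3 array turned, homeobox genes alone passed (median -0.13, camera adjusted p = 0.00642).

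**Figure D5:**
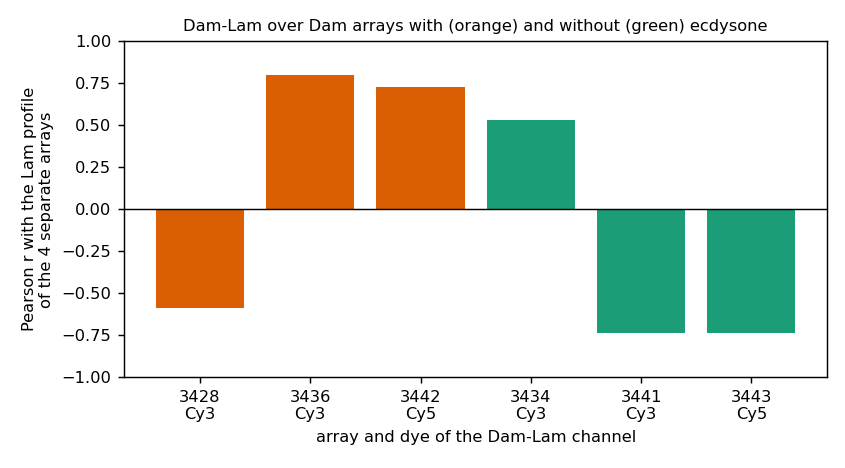
Pearson correlation across genes of each Dam-Lam over Dam array of the ecdysone experiment with the Lam profile of the 4 separate arrays, with ecdysone in orange and without in green, and the dye of the Dam-Lam channel under each bar. Arrays 3428, 3441 and 3443 are negative (-0.58, -0.74 and -0.74) and the other 3 positive (0.53 to 0.80).

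Genes whose transcripts rose with ecdysone had a median change of Lam ratio of 0.17 as deposited (154 genes, camera p = 0.00213, p = 0.156 with an estimated correlation) and of -0.08 with the 3 arrays turned. Those whose transcripts fell had -0.01 (n = 114 genes, camera p = 0.858), 0.09 without a dye term and 0.00033 with the arrays turned. Lam-higher genes had a median change of 0.43 as deposited (camera p = 1.24e-29, p = 0.199 with an estimated correlation) and -0.13 with the arrays turned. On the 2 arrays of Dam-Lam with over without ecdysone, which do not rest on those 6, their medians were -0.05 and -0.03. Across genes, rho between the mRNA change and the Lam change was 0.24 as deposited, -0.10 with the 3 arrays turned and 0.14 with every Cy3 array turned.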

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

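All tests of the signs of the ecdysone arrays were chosen after the result was seen, and the reading of the last was changed after its value was seen, with 3 readings tried. Of the 6 Dam-Lam over Dam arrays of the ecdysone experiment, 3428, 3441 and 3443 correlate negatively with the separate Lam profile and the other 3 positively. The tables argue against values left as Cy5 over Cy3, since the sign follows the dye on 3 of 6 arrays, and against a Lam profile reversed by ecdysone, since at most 4 of 6 arrays follow the treatment. If single arrays had been turned round at deposition, a dye profile taken from the TSA arrays should be turned with them, and 2 of 6 arrays had the turned sign. The mean slope on that profile was 0.01 on these arrays and 0.49 on the 4 direct arrays of the experiment. The difference of 0.48, with an SE of 0.29, lies under the limit of 2 SE, so the slope cannot tell turned from unturned arrays. Arrays of the same group and dye correlate at -0.64 (3428 and 3436) and -0.56 (3434 and 3441). That argues against 1 direction for all 6 arrays. Which of them run against their labels, and how, stays open.

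For the lower Lam ratios of Lam-higher genes with TSA, the tests of the slope and of Dam were chosen after the result was seen, and that of the rebuilt median before its value was known. The median change of -0.47 rests on the direct arrays of treated against untreated DNA and does not use the 2 Dam-Lam over Dam arrays with TSA. The untreated profile rebuilt from the TSA arrays had a slope of 0.858 on the separate one and a median of 0.82 at these genes. It is the treated ratio minus the TSA change, so it holds the change in question. Neither value can therefore decide on a flatter Lam profile throughout the TSA experiment or on genes called by chance. The 4 untreated arrays that called the genes do not enter the change of -0.47, so chance on them did not produce it. A rise of the Dam background, which is subtracted, is argued against by a median Dam change of -0.17 at these genes (-0.10 and -0.24 on the 2 Dam arrays). Whether Lam contact or the amount of Dam-Lam in treated cells accounts for it stays open.

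For the rows with very low Lam delta CaaX ratios, the tests below were written before their values were known, for a group picked from the data. At 21 rows the ratio was at or below -2, among them Ndg, ATPsynC, CG30457, rsh and Spt3, and 19 of them were below 0 with Lam too. Not all of these were called lower with Lam. ssx (-0.0099), Mlc2 (-0.12), pigeon (-0.24), dor (-0.25), ATPsynC (-0.37), CG3104 (-0.55) and mRpL37 (-0.88) did not pass. Of the rows not below 0, Alk was above 0 with Lam (1.34) and chb was not measured in that fit. Adjacent genes in the same domains do not explain them, because 11.8% of the 17 placed genes had another member within 2 measured genes. Under 1 shared source of signal, which could be DNA carried by the Dam plasmids, the rows would move together on the 24 DamID arrays that did not pick them, and the mean pairwise correlation there was 0.286, above the highest of 1000 random sets (0.181) but below the 0.5 set for it, against -0.016 on the mRNA arrays. Whether the rows have such a source or low binding of Lam delta CaaX cannot be told apart. For some rows, such as ATPsynC, pigeon and Alk, the TSA experiment did not show the low untreated ratio, which rests on the 4 separate arrays. For others, such as Ndg and rsh, it did. Their Lam delta CaaX signal rose by 2.11 and 2.14 with TSA and still lay at -0.73 and -0.76 over Dam.

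Of 35 splits of the 8 untreated arrays into 4 and 4, fitted without a dye term, 1 called as many genes as the real one. That was the real split itself, with 2704 genes, and the highest other called 0. Any other difference between the Lam and Lam delta CaaX arrays would give the same result. The 6 Dam-Lam over Dam arrays of the ecdysone experiment give 10 splits into 3 and 3, too few for a share under 0.05. With limma, the real split called 0 genes, as few as any, so all 10 called as many, and the highest other, arrays 3428, 3441 and 3443 against the rest, called 2963. Those are the arrays that correlate negatively with the separate Lam profile, so this split restates the open question of their direction.

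Single arrays far from the others of their group were looked for in 145 values by Dixon's test, where about 1 in 20, or 7.25, would be found by chance, and 11 were. Array 2945 gave CG10750 5.69, sls 4.24 and Parp1 -5.85 with Lam, and its values had an SD of 0.892. Array 3427 gave mRNA changes of 1.71 for NT5E-2, 2.14 for Hsp27, -0.43 for CG10512, -0.44 for RpL23, -0.81 for Dbct and 0.074 for eater. The SD of array 3452 was 0.399. Between the proteins, the TSA change was higher for Lam at 1342 genes and lower at 1354, with a median difference of -0.60 at Lam-higher genes and 0.30 at Lam delta CaaX-higher genes.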

How the results depend on the processing

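Leaving out single arrays moved the counts of called genes widely. For Lam they ran from 7 to 2207 higher and 4 to 2031 lower, for Lam delta CaaX from 476 to 1678 and 551 to 1688, and for their difference from 1295 to 1716 and 633 to 1175. With TSA they ran from 219 to 974 and 497 to 1331 for Lam, 399 to 1221 and 695 to 1513 for Lam delta CaaX, and 356 to 1177 and 546 to 1188 for Dam. The difference between the TSA changes gave 277 to 1734 higher and 687 to 1569 lower. Ecdysone mRNA counts ran from 55 to 353 and 29 to 456. Named values of uncalled genes that changed sign without an array had these ranges over the arrays left out. With Lam, MsrA ran from -0.018 (without 2945) to 0.16. In the ecdysone effect on Lam, EcR ran from -0.12 to 0.052 (without 3434; 0.047 without 3436 and 0.018 without 3465), MsrA from -0.14 (without 3441; -0.033 without 3436) to 0.25, and br reached 0.0069 without 3443. In that on Dam, EcR ran from -0.19 to 0.048 (without 3637). In the TSA effect on Lam, br ran from -0.091 (without 3691) to 0.13, and in that on Lam delta CaaX, EcR fell to -0.020 without 3692. The cause was not tested.

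With the 3 ecdysone-free arrays added to the Lam fit, limma called 0 higher and 0 lower (215 at an unadjusted p under 0.05), and ImpE1 (-0.0089), ND-B14.5AL (-0.060) and MsrA (-0.040) changed sign. Since 2 of those arrays have the opposite sign, this follows from the direction question. With the arrays scaled to the same spread, the ecdysone effect on Lam at EcR was 0.0082. From only the 4 direct arrays it was 0.075 at EcR, 0.12 at br and -0.0060 at MsrA. With 3 arrays turned round, the ecdysone change of Lam-higher genes went from 0.43 to -0.13, of mRNA-higher genes from 0.17 to -0.075, of mRNA-lower genes from -0.01 to 0.00033, and MsrA to -0.29. Without a dye term the mRNA-lower genes were at 0.088. With every Cy3 array turned, EcR was at 0.17 and MsrA at -0.15 for Lam, and br at -0.10 and MsrA at 0.27 for Dam.

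Against the separate untreated arrays, limma called 0 higher and 0 lower TSA changes for Lam (1137 at an unadjusted p under 0.05) and 88 and 125 for Lam delta CaaX. For Lam, mRpL37 (-0.16), Cht5 (-0.031), Acp53Ea (0.24) and br (-0.17) changed sign. For Lam delta CaaX these were shd (-0.37), Prosbeta2 (0.77), ATPsynC (2.82 against -0.77 in the main fit, called in both), Nrg (-0.045), up (-0.031), Acp65Aa (-0.024), Obp18a (0.22), lambdaTry (-0.056), zetaTry (0.046), Sgs5 (-0.0018), inv (-0.016) and EcR (-0.65), of which only ATPsynC was called against the separate arrays. The cause was not tested. Without a dye term, 848 genes had a higher TSA change for Lam than for Lam delta CaaX.

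With a correlation estimated per list, the lists called by camera went from 9 to 0 for Lam, 5 to 0 for Lam delta CaaX, 12 to 0 for their difference, 3 and 5 to 0 and 0 for the ecdysone effects on Lam and Dam, 2, 3 and 3 to 0, 0 and 0 for the TSA effects on Lam, Lam delta CaaX and Dam, and 3 to 0 for mRNA. With Lam, the estimated correlation was -0.037 for neuronal, -0.044 for muscle and 0.157 for oxidative phosphorylation genes. Correlation within a list therefore does not account for the loss of every list. That test also has only the few residual degrees of freedom of a fit, so its failure does not decide against a list. Of 706 named values, 252 kept their sign and their side of the threshold under every alternative, 440 lost significance under at least 1, and 25 changed sign. No paired analysis was possible because each array number is unique and the labels do not tie an array of a group to one of another.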

Other observations

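Genes whose mRNA rose with ecdysone were higher with Lam in untreated cells more often than the other genes. Of 150 genes with higher mRNA after ecdysone, 44 (29.3%) were higher with Lam in untreated cells, an odds ratio of 1.72 (95% interval 1.18 to 2.49), and of 2.11 (1.45 to 3.08) within 10 groups of equal mRNA level. Of 105 genes with lower mRNA after ecdysone, 22 (21.0%) were higher with Lam, against 20.3% of the others. With Lam delta CaaX, 42 of 152 genes with higher mRNA (27.6%) were higher, against 15.9% of the others, and 42 of 107 with lower mRNA (39.3%), against 15.8%. With TSA, genes with higher mRNA after ecdysone had median changes of -0.25 for Lam and -0.21 for Lam delta CaaX, and genes with lower mRNA -0.18 and -0.31. These comparisons were chosen after the values were seen. The intervals treat genes as independent, although genes higher with Lam lay next to each other, so they may be too narrow.

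The share of genes higher with Lam differed between the cDNA libraries named by the clone prefixes. In the AT library, from adult testis, 257 of 767 genes (33.5%) were higher with Lam, against 10.1% of LD genes and 12.02% of GM genes. The odds ratio of the AT genes was 2.18, and 1.23 (95% interval 1.04 to 1.46) within groups of equal mRNA level, so most of the excess went with low mRNA. The HL library had 39.8% of 83 genes higher with Lam, LP 30.8%, GH 28.2%, RE 21.9%, SD 14.1% and RH 12.96%. Median log2 mRNA level was -1.27 for AT, -1.14 for LP, 0.78 for LD and 1.16 for GM, but 0.64 for HL. GH (-0.52) and RH (-0.46) differed in share at similar levels, so the share did not follow mRNA level in every library. On chromosome 4, 15 of 46 genes (32.6%) were higher with Lam (Fisher's exact p = 0.0426), on 3L 22.4% (p = 0.0303) and on 2R 18.0% (p = 0.0209), two-sided and not adjusted over the 6 arms. These tabulations were also chosen after the values were seen, and genes are not independent replicates.

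The slope of the treated on the untreated profile was 0.364 for Lam and 0.0679 for Lam delta CaaX. The untreated profiles rebuilt from the TSA experiment had slopes of 0.858 (r = 0.84) for Lam and 0.628 (r = 0.64) for Lam delta CaaX on the separate ones. These slopes were chosen after the values were seen. A dye-swapped comparison of Dam-Lam with Dam-Lam delta CaaX on the same arrays, with and without TSA, would compare the proteins directly.

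The limits are those of the design. Groups have 2 to 5 arrays, the labels name no cultures, and counts of called genes moved widely when an array was left out. Log base and centring rest on the values. Direction rests on the values and on the assumed channel order of the labels, and the ecdysone DamID direction is open. Probes are cDNA clones, so ratios describe transcribed sequences and leave out the DNA between genes. Gene lists were assembled by symbol, and no list passed with an estimated correlation, a test with few degrees of freedom at these numbers of arrays.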
